A study of Mus musculus with 12 samples.

How the data were processed

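Messenger RNA was measured by sequencing in 12 libraries of mpkCCDc11 cells, a mouse cell line of the kidney cortical collecting duct, the part of the tubule in which vasopressin controls water reabsorption. Per the labels, the cells received a control siRNA or an siRNA against TAZ, the Hippo coactivator encoded by Wwtr1, and then vehicle or dDAVP, a synthetic vasopressin analogue, at 1e-09 M on the basolateral side. Each of the 4 combinations has 3 libraries. The labels list several exposure times to dDAVP for the series and do not say which one these libraries had, so the time is left open. They also do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

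The labels' protocols name a TruSeq stranded mRNA kit, and another TruSeq RNA kit beside it. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm10, with no role for any of them, and the counting tool is not given in the sources used here. The authors deposited an estimated count per gene and per transcript, written as whole numbers and not normalised, per the file headers and the values. The deposited gene counts equalled the sum of the transcript counts in all but 12 of 549324 gene and library values. The FPKM values that the authors deposited per transcript, per the file headers, served to check how the counts were made. All transcript counts of at least 1000 lay within 1% of the product of FPKM, transcript length and 1 factor per library, as any count from which an FPKM was made would. For counts of 2 to 20 that product was not whole (by over 0.05) in 85.6% of 157342 values, and 100% of the counts were that product rounded up, within 0.05. The counts are therefore rounded estimates per transcript and not tallies. How reads of similar genes were divided is not given in the sources used here, so values of genes with near-identical copies are uncertain. Whether a count stands for a read or a read pair is not given in the sources used here. Another 36 columns of per-sample values were not used. Coordinates are those of the transcript table, and those of Aqp2 and Wwtr1 equalled the RefSeq annotation of GRCm38.

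The design had assumed whole read counts or a normalised unit. The deposited values are estimated counts already written as whole numbers, so no rounding was needed and the test for counts was kept. Of 45777 genes, 24656 had a count in at least 1 library and 15932 passed the filter of edgeR (filterByExpr, minimum count 10, on the 4 groups). Tested genes held 99.98% of all counts. Library totals ran from 45095300 to 61725300 counts, and the coefficient of biological variation was 5.11%. A count of 3 in 1 library corresponds to between 0.0486 and 0.0665 CPM, the unit in which counts are scaled to the library total, and intervals from counts cover counting error only. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 4.25 to 13.5), so all 12 were kept as separate samples.

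Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Normalisation used TMM factors, which lay between 0.988 and 1.01. A model with 1 mean per group was fitted to all 12 libraries by robust quasi-likelihood, because each group has only 3 libraries. The quasi-likelihood F test gave 5 contrasts, which were the response to dDAVP with each siRNA, the effect of the TAZ siRNA in each treatment, and the difference of the dDAVP responses between the siRNAs. Unless another tool is named, an adjusted p of a gene comes from this test with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given ± a standard error, and CPM as mean ± SD over 3 libraries. That standard error was not estimated directly but derived from the fold change and its F statistic, and the bound given for Yap1 rests on it.

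A set of 22 gene lists was fixed before the data were examined, along with the groups, the tests, the rule for named genes and the alternatives. The lists cover principal cell transport, transcription factors linked to Aqp2, cAMP and CREB targets, AQP2 trafficking and cAMP signalling, YAP and TAZ targets, Hippo components, cell cycle, interferon response, NF-kappaB and cytokines, extracellular matrix, actin and focal adhesion, epithelial junctions, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, p53 targets, NRF2 and glutathione, Notch, WNT and TGF-beta feedback, and markers of intercalated cells, of other nephron segments, and of fibroblast, endothelial and immune cells. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists of a contrast, and again with an estimated correlation. Members were also counted after an adjustment over the list alone. Genes named always were Wwtr1, Taz, Yap1, Aqp2, Aqp3, Aqp4, Avpr2, Scnn1a, Scnn1b, Scnn1g, Gata2, Gata3, Elf3, Elf5, Nfatc1, Nfat5, Creb1, Ccn1, Ccn2 and Ankrd1. Further named genes were, per contrast, up to 12 called genes with the highest and 12 with the lowest log2 fold change (6 and 6 for the difference of responses), with a mean of at least 1 CPM, no overlap of the library values of the groups compared and no predicted gene model. Up to 4 members of each list with the smallest adjusted p could also be named.

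The procedure was tested on simulated counts with known changes before use. For the effect of the TAZ siRNA with vehicle, 72% of genes with the smallest simulated change, 82% of genes changed 1.5-fold, 96% of those changed 2-fold and 98% of those changed 4-fold were called among 15932 genes, with 19 unchanged genes called. For the difference of responses the shares were 54%, 76%, 90% and 100%, with 12 unchanged genes called. The changed genes were drawn from genes with a mean of at least 1 CPM, so the shares do not cover lower genes. Of 50 genes per size of change, 36, 41, 48 and 49 were called in the first case and 27, 38, 45 and 50 in the second. In both cases unchanged genes thus made up a share above 0.05 of the calls. Alternatives were median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in at least 6 libraries, fits on the compared groups alone, the replicate number as a block, leaving out each library in turn, and for the lists the estimated correlation and fry. Figures were drawn with matplotlib 3.10.9.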

Results

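RNA was sequenced from 12 libraries of mpkCCDc11 cells, a mouse line of the kidney cortical collecting duct that carries the vasopressin V2 receptor. The series addressed how TAZ acts on aquaporin-2, the vasopressin-regulated water channel of the apical membrane. Cells had received control siRNA or TAZ siRNA and then vehicle or 1e-09 M dDAVP, a V2 receptor agonist, with 3 libraries in each of the 4 groups. Total counts per library were 47072900 to 58226100 with control siRNA and vehicle and 55232000 to 61505600 with control siRNA and dDAVP. They were 60715300 to 61725300 with TAZ siRNA and vehicle and 45095300 to 59448800 with TAZ siRNA and dDAVP. Changes are log2 fold changes ± SE with 3 libraries per group. Adjusted p-values of genes are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists are from camera.

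The targeted gene was lower in each of the 6 TAZ siRNA libraries than in any of the 6 control libraries. Wwtr1 (gene identifier 97064, chromosome 3 from 57455644 to 57575910 in the mm10 coordinates of the transcript table) encodes TAZ. It fell from 181 ± 4.4 to 116 ± 2.5 CPM with vehicle (-0.63 ± 0.05, adjusted p = 4e-06). With dDAVP it fell from 166 ± 6.6 to 114 ± 11 CPM (-0.54 ± 0.05, adjusted p = 5.54e-06). The ratios to control were 0.645 and 0.686. One transcript model, NM_133784, carried 97.0% to 99.4% of the Wwtr1 counts in the 4 groups. The gene named Taz in the files, which encodes tafazzin of the mitochondria, was at 19.9 ± 1.5 and 19.7 ± 1.0 CPM with vehicle (adjusted p = 0.936). Yap1, which encodes the paralogue of TAZ, was at 171 ± 4.3 and 170 ± 1.2 CPM (adjusted p = 0.92). With dDAVP the adjusted p of Taz was 0.431 and that of Yap1 was 0.837.

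**Figure D1:**
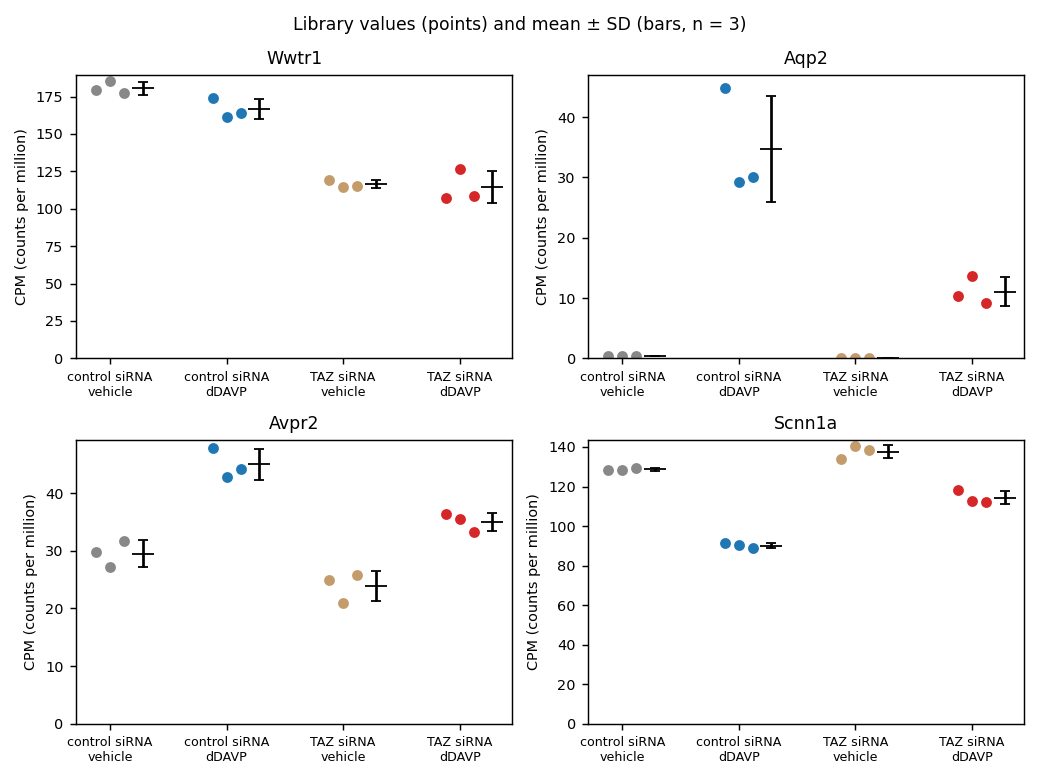
CPM of Wwtr1, Aqp2, Avpr2 and Scnn1a in each of the 12 libraries (points), with mean and SD per group of 3 libraries. Wwtr1 lay between 108 and 127 CPM in the TAZ siRNA libraries and between 161 and 186 CPM in the control siRNA libraries. Aqp2 reached 34.7 ± 8.8 CPM with control siRNA and dDAVP but 11.0 ± 2.4 CPM with TAZ siRNA and dDAVP.

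The first comparison asked what dDAVP changed in cells with control siRNA. Aqp2 (gene identifier 11827, chromosome 15 from 99579056 to 99584545, with NM_009699 as its only transcript in the table) rose from 0.34 ± 0.0034 to 34.7 ± 8.8 CPM, a change of 6.66 ± 0.34 (adjusted p = 1.23e-07). The summed counts were 55 with vehicle and 6036 with dDAVP, a ratio of 102 with a counting interval of 78.3 to 136. Avpr2, the V2 receptor, rose by 0.61 ± 0.07. Scnn1a, the alpha subunit of the epithelial sodium channel, fell from 129 ± 0.57 to 90.1 ± 1.2 CPM (-0.51 ± 0.03, adjusted p = 2.34e-09). The cAMP phosphodiesterases Pde4b (3.78 ± 0.09) and Pde4d (2.47 ± 0.09) and the orphan nuclear receptors Nr4a3 (3.68 ± 0.29) and Nr4a1 (1.97 ± 0.07) were among the most raised genes. The test called 3058 of 15932 genes, 1548 higher and 1510 lower, of which 160 rose and 42 fell at least 2-fold. Without control siRNA vehicle replicate 2 it called 1036 higher and 1093 lower.

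Of the other genes named for their size of change, Baiap2l2 (3.51 ± 0.10), B3gnt7 (2.63 ± 0.10), Nipal1 (2.28 ± 0.08), Sprr2g (2.21 ± 0.17), Aqp5, another aquaporin (2.20 ± 0.11), Nod2 (2.03 ± 0.08) and Scg5 (1.99 ± 0.26) rose. Ugt1a6a rose by 2.94 ± 0.22, and its counts can be shared with neighbouring Ugt1a genes. Antxr1 (-1.52 ± 0.13), Heyl, a Notch target (-1.52 ± 0.17), P3h2, a collagen prolyl hydroxylase (-1.28 ± 0.06), Rasl11a (-1.22 ± 0.12), Myo3b (-1.18 ± 0.22) and Fgf18 (-1.14 ± 0.10) fell. So did Lhx4 (-1.13 ± 0.17), Masp1 (-1.08 ± 0.15), Trabd2b (-1.05 ± 0.16), Ccdc141 (-1.05 ± 0.22) and Cdsn (-1.65 ± 0.33). Among genes named in advance, the transcription factor Elf3 rose by 0.35 ± 0.04 (adjusted p = 2.44e-06) and Nfat5, the tonicity-responsive factor, fell by 0.31 ± 0.05 (adjusted p = 0.000366). Aqp3, a basolateral water channel at 0.513 ± 0.089 CPM with vehicle, rose by 0.99 ± 0.28 (adjusted p = 0.0189). Its adjusted p was 0.0697 without control siRNA vehicle replicate 1, 0.066 without replicate 3 and 0.0743 without control siRNA dDAVP replicate 2. Gata3 rose by 0.20 ± 0.05 (adjusted p = 0.0138), with 0.0826 without control siRNA vehicle replicate 2. Adjusted p-values were 0.323 for Scnn1b, 0.837 for Scnn1g, 0.686 for Gata2, 0.517 for Nfatc1, 0.149 for Creb1 (0.0424 without control siRNA vehicle replicate 3), 0.123 for Ccn1 and 0.193 for Ankrd1. Ccn2, a YAP and TAZ target, fell by 0.16 ± 0.05 (adjusted p = 0.0368). Its adjusted p was 0.169 without control siRNA vehicle replicate 2, 0.188 and 0.0719 without control siRNA dDAVP replicates 1 and 3, and 0.0502 in limma-voom. Aqp4 (0.124 ± 0.016 CPM with vehicle) and Elf5 (0.0741 ± 0.069 CPM) were too low to be tested.

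By gene group, 18 of 23 cAMP and CREB target genes rose and 2 fell (19 and 2 adjusted over the list alone, camera adjusted p = 4.63e-52). Of 20 NRF2 and glutathione genes 19 rose (19 adjusted over the list alone, adjusted p = 2.04e-37). They were led by the metallothionein Mt2 (1.46 ± 0.07), Srxn1 (0.72 ± 0.05) and Gclc, which limits glutathione synthesis (0.58 ± 0.05). Extracellular matrix genes fell in 9 of 19 members and rose in 1 (11 and 2 adjusted over the list alone, adjusted p = 9.75e-10). The basement membrane chains Col4a1 (-0.64 ± 0.03) and Col4a2 (-0.69 ± 0.04) were among those that fell. Of 5 tested markers of other nephron segments, Podxl (-0.71 ± 0.04) and Lrp2 (-0.21 ± 0.05) fell (2 adjusted over the list alone, adjusted p = 0.00047). These 4 calls held with an estimated correlation, at adjusted p-values of 0.000218, 0.000626, 0.0182 and 0.0292.

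Other groups passed camera at the preset correlation but not with an estimated correlation. Principal cell transport genes rose in 10 of 18 members and fell in 2 (10 and 2 adjusted over the list alone, adjusted p = 3.83e-05, and adjusted p = 0.0908 with an estimated correlation). Atp1b1, a sodium pump subunit, rose by 0.79 ± 0.04 and St6gal1 fell (-0.99 ± 0.05). Glycolysis and hypoxia genes rose in 14 of 23 members (14 adjusted over the list alone, adjusted p = 2.81e-08, and adjusted p = 0.154 with an estimated correlation). Ndrg1 (0.68 ± 0.06) and Ldha (0.59 ± 0.06) were among them. Cell cycle genes fell in 11 of 28 and rose in 2 (16 and 2 adjusted over the list alone, adjusted p = 5.64e-05, and adjusted p = 0.1 with an estimated correlation), including Top2a (-0.27 ± 0.03). Of 24 Hippo components 11 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.00047, and adjusted p = 0.109 with an estimated correlation). Of 23 YAP and TAZ targets 10 fell and 3 rose (13 and 5 adjusted over the list alone, adjusted p = 0.0031, and adjusted p = 0.109 with an estimated correlation). Amotl2 changed by -0.48 ± 0.03 and Dock5 by 0.80 ± 0.04. Cholesterol synthesis genes fell in 9 of 21 (10 adjusted over the list alone, adjusted p = 0.00047, and adjusted p = 0.279 with an estimated correlation). Intercalated cell markers rose in 3 of 9 (5 adjusted over the list alone, adjusted p = 0.000428, and adjusted p = 0.0571 with an estimated correlation). They included Car2 (0.57 ± 0.04) and Aqp6 (1.08 ± 0.11).

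NF-kappaB and cytokine genes rose in 5 of 19 and fell in 2 (8 and 3 adjusted over the list alone, adjusted p = 0.000757, and adjusted p = 0.0908 with an estimated correlation). Complement C3 (1.26 ± 0.06) and the chemokine Cxcl5 (1.69 ± 0.13) rose. Oxidative phosphorylation genes rose in 7 of 24 (13 adjusted over the list alone, adjusted p = 0.00082, and adjusted p = 0.373 with an estimated correlation). Epithelial junction genes rose in 9 of 27 and fell in 4 (10 and 5 adjusted over the list alone, adjusted p = 0.00235, and adjusted p = 0.153 with an estimated correlation). The median of this list was -0.01, against a mean of 0.08 and a test for higher values, and the keratins Krt19 (0.79 ± 0.05), Krt18 (0.67 ± 0.04) and Krt8 (0.56 ± 0.05) rose. Notch, WNT and TGF-beta feedback genes fell in 6 of 20 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.00441, and adjusted p = 0.0525 with an estimated correlation). Unfolded protein response genes rose in 7 of 22 and fell in 2 (9 and 3 adjusted over the list alone, adjusted p = 0.00941, and adjusted p = 0.153 with an estimated correlation), including Sesn2 (0.62 ± 0.06). AQP2 trafficking and cAMP signalling components rose in 8 of 27 and fell in 3 (11 and 4 adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.27 with an estimated correlation). This call was lost without control siRNA vehicle replicate 2 (adjusted p = 0.065) or control siRNA dDAVP replicate 1 (adjusted p = 0.0561). Transcription factors linked to Aqp2 (10 higher and 8 lower of 33, adjusted p = 0.534), actin (4 and 8 of 26, adjusted p = 0.16), p53 (7 and 2 of 23, adjusted p = 0.0617) and interferon genes (2 and 2 of 25, adjusted p = 0.53) did not pass as lists. Adjusted over the list alone, these 4 had 11 and 9, 5 and 8, 8 and 4, and 2 and 2 members called higher and lower. The actin list had a median of 0.0031 and a mean of -0.03. Of 7 fibroblast, endothelial and immune markers the smallest adjusted p was 0.0683, for Cd74 (-0.67 ± 0.25, and 0.0464 in a fit of the compared groups alone), and the list did not pass (0 adjusted over the list alone, camera adjusted p = 0.53).

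The second comparison asked what dDAVP changed in cells with TAZ siRNA. Aqp2 rose from 0.0484 ± 0.084 to 11.0 ± 2.4 CPM (7.76 ± 0.49, adjusted p = 1.39e-06). The vehicle level rested on 9 counts, all in replicate 1, against 1669 counts with dDAVP, a ratio of 226 with a counting interval of 119 to 495. Avpr2 rose by 0.56 ± 0.07, and Scnn1a fell from 138 ± 3.3 to 114 ± 3.3 CPM (-0.27 ± 0.03). Pde4b (3.52 ± 0.09), Nr4a3 (3.62 ± 0.29), Baiap2l2 (3.43 ± 0.10), Pde4d (2.21 ± 0.09), B3gnt7 (2.13 ± 0.11), Krt23 (1.98 ± 0.26), Nipal1 (1.95 ± 0.09), Aqp5 (1.83 ± 0.11), and Sult1d1 (1.78 ± 0.23) rose. Ugt1a6a (3.05 ± 0.23) and Gsdmc4 (1.82 ± 0.23), from families of near-identical genes, are uncertain. Trmt61b (-1.65 ± 0.24), Cdsn (-1.50 ± 0.27), Heyl (-1.20 ± 0.17), Myo3b (-1.12 ± 0.22), Trabd2b (-1.11 ± 0.16) and Antxr1 (-1.10 ± 0.13) fell. So did Rasl11a (-1.10 ± 0.12), Nrxn2 (-1.07 ± 0.19), Nlrc3 (-0.96 ± 0.19), Fgf18 (-0.95 ± 0.10) and P3h2 (-0.93 ± 0.06).

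Elf3 rose by 0.37 ± 0.04 (adjusted p = 2.76e-06) and Ankrd1, a YAP and TAZ target, fell by 0.33 ± 0.07 (adjusted p = 0.00451). Gata3 rose by 0.21 ± 0.05 (adjusted p = 0.0143), with 0.0944 and 0.0545 without TAZ siRNA vehicle replicates 2 and 3, 0.0693 without TAZ siRNA dDAVP replicate 2 and 0.0501 in a fit of the compared groups alone. Nfat5 fell by 0.18 ± 0.05 (adjusted p = 0.0326), with 0.123 and 0.0734 without TAZ siRNA vehicle replicates 1 and 2, 0.153 and 0.134 without TAZ siRNA dDAVP replicates 1 and 3 and 0.0587 in the fit of the compared groups. Adjusted p-values were 0.652 for Aqp3, 0.238 for Scnn1b, 0.693 for Scnn1g, 0.619 for Gata2, 0.548 for Nfatc1, 0.352 for Creb1, 0.149 for Ccn1 and 0.813 for Ccn2 in edgeR. Without TAZ siRNA vehicle replicate 1 Scnn1b (0.0274) and Ccn1 (0.0415) passed, and Ccn1 also did in the fit of the compared groups (0.0434). The test called 1719 of 15932 genes, 1016 higher and 703 lower, with 96 raised and 18 lowered at least 2-fold. With no low-count filter 809 were higher and 854 lower. Without TAZ siRNA vehicle replicate 2 the count was 1129. Replicates 2 and 3 with TAZ siRNA and dDAVP, at 47393500 and 45095300 counts, stood at opposite ends of the third principal component (-32.2 and 20.4, 9.67% of the variance).

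The cAMP and CREB targets rose in 15 of 23 members and fell in 1 (18 and 1 adjusted over the list alone, adjusted p = 1.71e-51). NRF2 and glutathione genes rose in 16 of 20 (18 higher and 1 lower adjusted over the list alone, adjusted p = 7.04e-28), with Mt2 at 1.10 ± 0.07 and Srxn1 at 0.61 ± 0.05. Extracellular matrix genes fell in 7 of 19 and rose in 1 (7 and 1 adjusted over the list alone, adjusted p = 8.58e-08). Principal cell transport genes rose in 8 of 18 and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 8.58e-08). Intercalated cell markers rose in 5 of 9 (5 adjusted over the list alone, adjusted p = 2.61e-05), led by Aqp6 (1.30 ± 0.11). Of 5 markers of other nephron segments 2 fell (2 adjusted over the list alone, adjusted p = 0.000862), among them Podxl (-0.46 ± 0.03). With an estimated correlation these 6 lists kept adjusted p-values of 0.000195, 0.00205, 0.0338, 0.0338, 0.0338 and 0.0338.

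Cholesterol synthesis genes fell in 10 of 21 (14 adjusted over the list alone, adjusted p = 1.4e-09, and adjusted p = 0.137 with an estimated correlation). Idi1 (-0.39 ± 0.05) and Hmgcs1 (-0.27 ± 0.04) were among them. Cell cycle genes fell in 11 of 28 and rose in 1 (16 and 5 adjusted over the list alone, adjusted p = 0.000862, and adjusted p = 0.191 with an estimated correlation). Glycolysis and hypoxia genes rose in 5 of 23 (7 adjusted over the list alone, adjusted p = 0.00166, and adjusted p = 0.415 with an estimated correlation). Of 24 Hippo components 6 fell (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.00421, and adjusted p = 0.197 with an estimated correlation). Epithelial junction genes rose in 9 of 27 and fell in 3 (10 and 3 adjusted over the list alone, adjusted p = 0.00733, and adjusted p = 0.259 with an estimated correlation). A further 7 lists passed narrowly, with adjusted p-values of 0.0209 to 0.0479 at the preset correlation and 0.137 to 0.558 with an estimated correlation. Interferon genes rose in 5 of 25 (5 adjusted over the list alone), AQP2 trafficking genes rose in 6 and fell in 1 of 27 (7 and 1) and oxidative phosphorylation genes rose in 1 of 24 (0). Actin and focal adhesion genes fell in 6 and rose in 1 of 26 (9 and 2 adjusted over the list alone), and Notch, WNT and TGF-beta feedback genes fell in 4 and rose in 1 of 20 (5 and 1). Transcription factors linked to Aqp2 rose in 10 and fell in 4 of 33 (12 and 4 adjusted over the list alone), and YAP and TAZ targets fell in 8 and rose in 3 of 23 (8 and 4).

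Each of these 7 calls ended without 1 of several libraries. Without TAZ siRNA vehicle replicate 3 the adjusted p was 0.169 for interferon, 0.0553 for AQP2 trafficking and for Notch feedback, 0.318 for actin, 0.173 for the transcription factors and 0.117 for YAP and TAZ targets. Without vehicle replicate 1 it was 0.188 for oxidative phosphorylation. Without vehicle replicate 2 it was 0.0553 for Notch feedback and 0.064 for YAP and TAZ targets. Without TAZ siRNA dDAVP replicate 1 it was 0.151 for oxidative phosphorylation and 0.0852 for YAP and TAZ targets, and without replicate 2 it was 0.0746 for actin, 0.0792 for AQP2 trafficking and 0.199 for the transcription factors. Without replicate 3 it was 0.106 for actin and for oxidative phosphorylation, 0.333 for interferon, 0.0945 for Notch feedback and 0.131 for YAP and TAZ targets. NF-kappaB genes (5 higher and 2 lower of 19, adjusted p = 0.0906), the unfolded protein response (3 and 1 of 22, adjusted p = 0.0732), p53 targets (2 and 1 of 23, adjusted p = 0.582) and fibroblast, endothelial and immune markers (1 of 7 lower, adjusted p = 0.559) did not pass as lists. The NF-kappaB list had a median of -0.0062 and a mean of -0.02, while the test pointed to higher values.

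Between the siRNAs, 790 genes rose and 510 fell in both dDAVP responses, against 98.7 and 66.6 for independent lists of those sizes, and the responses share no library. Both responses came from 1 fit with a shared estimate of spread per gene. Their calls are thus not independent, and the overlap of independent lists may be too low a reference. Across the 15932 genes, which are not independent replicates, fold changes of both responses correlated with r = 0.376 and rho = 0.472. The 3 genes called in opposite directions, named after their values were seen, were Lyar (0.18 and -0.23), Phf11c (1.55 and -1.15) and Slc16a8, whose highest group mean was 0.238 CPM.

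**Figure D2:**
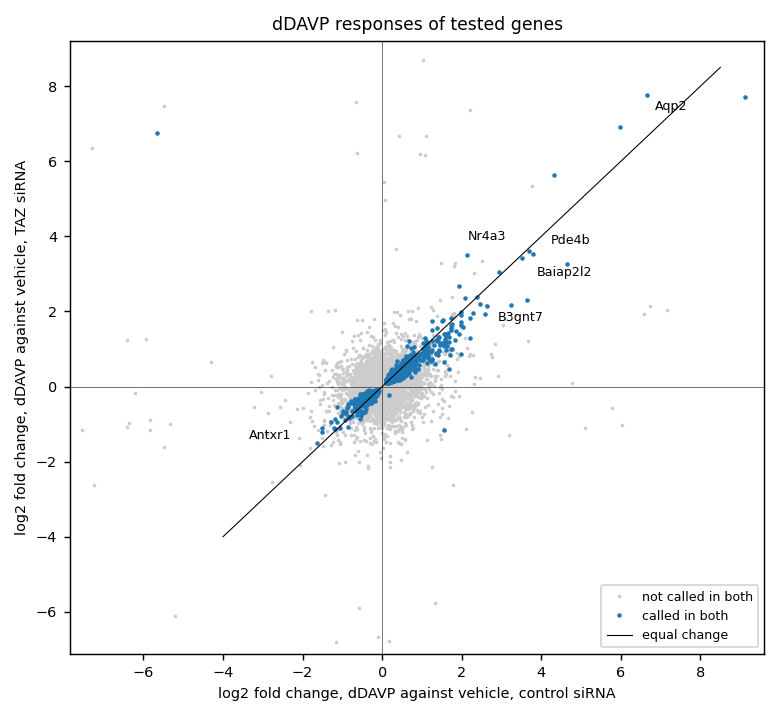
Log2 fold change of each of 15932 tested genes on dDAVP with control siRNA (horizontal) and with TAZ siRNA (vertical), with genes called in both responses in blue and a line of equal change. Of the blue genes 790 rose and 510 fell in both responses, such as Aqp2 (6.66 and 7.76) and Antxr1 (-1.52 and -1.10), and Lyar (0.18 and -0.23), Phf11c (1.55 and -1.15) and Slc16a8 (at most 0.238 CPM) went opposite ways.

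The third comparison asked what the TAZ siRNA changed without dDAVP. Glycolysis and hypoxia genes were lower as a group, with 20 of 23 members called lower and none higher (22 adjusted over the list alone), a median of -0.46 and a camera adjusted p of 3.17e-53 (0.0164 with an estimated correlation). They included lactate dehydrogenase Ldha (-0.58 ± 0.06), the phosphofructokinase Pfkl (-0.67 ± 0.06), Pfkfb3 (-0.62 ± 0.07), and Pdk1, which restrains pyruvate use in mitochondria (-0.80 ± 0.08). The mitophagy gene Bnip3 fell from 51.3 ± 10 to 23.0 ± 0.70 CPM (-1.15 ± 0.17). Ackr3, a chemokine receptor (-1.07 ± 0.09), Scube3 (-2.22 ± 0.27), Pamr1 (-1.80 ± 0.20) and the amino acid transporter Slc6a14 (-1.79 ± 0.23) fell as well. So did Casr, the calcium-sensing receptor (-1.47 ± 0.19), Rnf186 (-1.08 ± 0.15), Grin1 (-1.06 ± 0.15) and Depp1 (-1.04 ± 0.09). The cytokine genes Cxcl5 (0.83 ± 0.13), Ccl20 (1.28 ± 0.27) and Il1rn (0.88 ± 0.16) rose, with Phf11c (2.01 ± 0.37), Sema7a (0.83 ± 0.13) and Anxa8 (0.80 ± 0.16). Cdsn rose by 1.23 ± 0.26, with adjusted p-values of 0.0585 without control siRNA vehicle replicate 1 and 0.0674 without TAZ siRNA vehicle replicate 2.

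The edgeR test called 1004 of 15932 genes, 508 higher and 496 lower, and 683 higher and 384 lower with upper-quartile scaling. Lower calls were the more numerous with median-of-ratios scaling (477 higher and 500 lower) and DESeq2 (656 and 741). They were so too without control siRNA vehicle replicates 1 (232 and 276), 2 (356 and 421) and 3 (271 and 319) and TAZ siRNA vehicle replicates 1 (631 and 822), 2 (196 and 218) and 3 (232 and 285). At least 2-fold changes numbered 16 higher and 22 lower. The count was 508 without control siRNA vehicle replicate 1, 590 without replicate 3, 414 without TAZ siRNA vehicle replicate 2 and 517 without replicate 3.

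Aqp2 stood at 0.34 ± 0.0034 CPM with control siRNA (55 counts in all) and 0.0484 ± 0.084 CPM with TAZ siRNA (9 counts). The log2 fold change of -2.75 ± 1.02 did not pass in edgeR (adjusted p = 0.152) but did in DESeq2 (adjusted p = 0.000148). Over the alternatives the adjusted p ran up to 0.37, and the fold change was -7.25 without TAZ siRNA vehicle replicate 1, which held all 9 counts. The ratio of counts was 0.143, with a counting interval of 0.062 to 0.291. Avpr2 fell from 29.5 ± 2.3 to 23.8 ± 2.6 CPM (-0.31 ± 0.07, adjusted p = 0.0183), with adjusted p-values of 0.0665 without control siRNA vehicle replicate 1, 0.0798 without replicate 3 and 0.113 without TAZ siRNA vehicle replicate 2. Ankrd1 rose by 0.31 ± 0.07 (adjusted p = 0.0126), with 0.0699 and 0.0697 without control siRNA vehicle replicates 1 and 3 and 0.0886 and 0.0626 without TAZ siRNA vehicle replicates 2 and 3. Scnn1a was at 0.10 ± 0.03 (adjusted p = 0.0728), Gata2 at -0.50 ± 0.17 (adjusted p = 0.0876), Gata3 at -0.18 ± 0.05 (adjusted p = 0.0592), Elf3 at -0.12 ± 0.04 (adjusted p = 0.0706) and Creb1 at -0.14 ± 0.05 (adjusted p = 0.0921). Adjusted p-values were 0.821 for Aqp3, 0.106 for Scnn1b, 0.0596 for Scnn1g, 0.407 for Nfatc1 and 0.934 for Nfat5 in edgeR. DESeq2 called Scnn1a (0.0271), Scnn1g (0.0284), Gata3 (0.0249) and Elf3 (0.0277), and upper-quartile scaling Scnn1a (0.0343). Without TAZ siRNA vehicle replicate 1 Scnn1b (0.009), Scnn1g (0.0106), Gata3 (0.00252), Elf3 (0.024) and Creb1 (0.0281) passed. Gata2 passed without TAZ siRNA vehicle replicate 3 (0.00927), Scnn1g (0.0216) and Elf3 (0.0412) without control siRNA vehicle replicate 2 and Creb1 without replicate 3 (0.0414). The classical YAP and TAZ targets Ccn1 (-0.01 ± 0.11, adjusted p = 0.97) and Ccn2 (0.01 ± 0.05, adjusted p = 0.937) were not called.

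The YAP and TAZ target list had 5 members higher and 2 lower of 23 (5 and 4 adjusted over the list alone, median -0.01, mean -0.0065, and adjusted p = 0.857 in a test that pointed to higher values). Axl (0.45 ± 0.08), Dock5 (0.29 ± 0.04) and Myof (0.22 ± 0.03) rose and Tgfb2 fell (-0.58 ± 0.09). Target genes of p53 rose in 5 of 23 (11 adjusted over the list alone, adjusted p = 0.000128, and 0.0164 with an estimated correlation). Cholesterol synthesis and uptake genes rose in 13 of 21 and fell in none (18 and 0 adjusted over the list alone, adjusted p = 6.3e-17, and adjusted p = 0.0904 with an estimated correlation). Cyp51 (0.24 ± 0.04) and Idi1 (0.32 ± 0.05) were among them. NF-kappaB and cytokine genes rose in 8 of 19 and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.000128, and adjusted p = 0.0904 with an estimated correlation). Extracellular matrix genes rose in 3 of 19 (4 adjusted over the list alone, adjusted p = 0.00101, and adjusted p = 0.147 with an estimated correlation). Principal cell transport genes fell in 2 of 18 and rose in 1 (7 and 2 adjusted over the list alone, adjusted p = 0.00134, and adjusted p = 0.218 with an estimated correlation). Intercalated cell markers fell in 2 of 9 (3 adjusted over the list alone, adjusted p = 0.00365, and adjusted p = 0.147 with an estimated correlation), namely Aqp6 (-0.67 ± 0.11) and Rhcg (-0.50 ± 0.10).

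Actin and focal adhesion genes rose in 5 of 26 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.00101, and adjusted p = 0.408 with an estimated correlation). NRF2 and glutathione genes rose in 3 of 20 (5 adjusted over the list alone, adjusted p = 0.00365, and adjusted p = 0.261 with an estimated correlation). Transcription factors linked to Aqp2 fell in 4 of 33 and rose in 2 (12 and 3 adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.261 with an estimated correlation), with Jun at -0.42 ± 0.04 and Atf3 at 0.65 ± 0.10. Oxidative phosphorylation genes rose in 2 of 24 (4 adjusted over the list alone, adjusted p = 0.0182, and adjusted p = 0.743 with an estimated correlation). These 4 calls ended without 1 library. The adjusted p was 0.0555 for actin and 0.181 for oxidative phosphorylation without TAZ siRNA vehicle replicate 3. It was 0.0536 for NRF2 and 0.327 for oxidative phosphorylation without control siRNA vehicle replicate 2, and 0.105 for the transcription factors without control siRNA vehicle replicate 1. The remaining 10 lists did not pass, with adjusted p-values from 0.185 for cAMP targets and other nephron segments to 0.998 for interferon genes.

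The fourth comparison asked what the TAZ siRNA changed in the presence of dDAVP. Aqp2 was lower with TAZ siRNA, at 11.0 ± 2.4 against 34.7 ± 8.8 CPM (-1.66 ± 0.21, adjusted p = 0.000555). Avpr2 was lower as well, at 35.1 ± 1.6 CPM with TAZ siRNA (-0.36 ± 0.07, adjusted p = 0.00356). Scnn1a rose from 90.1 ± 1.2 to 114 ± 3.3 CPM (0.34 ± 0.03, adjusted p = 5.54e-06). Glycolysis and hypoxia genes fell in 21 of 23 members and rose in none (22 and 0 adjusted over the list alone, median -0.62, adjusted p = 1.21e-68, and 0.0126 with an estimated correlation). Ldha was at -0.84 ± 0.06, Pfkl at -0.82 ± 0.06, Aldoa at -0.75 ± 0.06 and Bnip3 at -1.30 ± 0.17.

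Egln3, an oxygen-sensing prolyl hydroxylase (-1.45 ± 0.24), Ankrd37 (-1.25 ± 0.27), Pamr1 (-2.31 ± 0.18), Scube3 (-1.92 ± 0.26), and Grin1 (-1.53 ± 0.16) fell too. So did the nucleoside transporter Slc28a3 (-1.50 ± 0.20), Trmt61b (-1.32 ± 0.24), Adgrf1 (-1.16 ± 0.20), Casr (-1.15 ± 0.19) and Krt23 (-1.15 ± 0.22). The raised genes included ccdc198 (0.90 ± 0.10), Hsd17b14 (0.87 ± 0.13), Npr3, a natriuretic peptide receptor (0.79 ± 0.10), Crb2 (0.75 ± 0.11), Ephb6 (0.74 ± 0.12) and Lmcd1 (0.72 ± 0.11). Rps27rt and Stmn1-rs2 also rose but resemble other loci and are uncertain. The adjusted p of Rps27rt was 0.105 and 0.0864 without control siRNA dDAVP replicates 1 and 3 and 0.12 and 0.0674 without TAZ siRNA dDAVP replicates 1 and 2. That of Stmn1-rs2 was 0.0633 without control siRNA dDAVP replicate 1 and 0.0756 without TAZ siRNA dDAVP replicate 3. The test called 1711 of 15932 genes, 919 higher and 792 lower, with 22 raised and 40 lowered at least 2-fold. Lower calls were the more numerous with no low-count filter (675 higher and 857 lower), with DESeq2 (958 and 1027), without control siRNA dDAVP replicate 2 (569 and 572) and without TAZ siRNA dDAVP replicate 2 (774 and 878). The count was 1067 without control siRNA dDAVP replicate 3, 1065 without TAZ siRNA dDAVP replicate 1 and 1093 without TAZ siRNA dDAVP replicate 3.

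Ccn2 rose by 0.20 ± 0.05 (adjusted p = 0.0188), with 0.105 without control siRNA dDAVP replicate 1 and 0.0577 and 0.079 without TAZ siRNA dDAVP replicates 1 and 3. Ccn1 (-0.02 ± 0.11, adjusted p = 0.932) and Ankrd1 (0.13 ± 0.07, adjusted p = 0.306) were not called, nor were Aqp3 (-0.89 ± 0.28, adjusted p = 0.0513), Gata2 (adjusted p = 0.0949), Gata3 (adjusted p = 0.0605), Elf3 (adjusted p = 0.0837), Nfat5 (adjusted p = 0.0963), Creb1 (adjusted p = 0.147), Scnn1b (adjusted p = 0.153), Scnn1g (adjusted p = 0.207) and Nfatc1 (adjusted p = 0.375) in edgeR. DESeq2 called Gata3 (0.0294) and Elf3 (0.0376), limma-voom Aqp3 (0.0394), and the fit of the compared groups alone Aqp3 (0.0456), Gata2 (0.0333) and Gata3 (0.0255). Without TAZ siRNA dDAVP replicate 2 Gata3 (0.0207) and Elf3 (0.0351) passed, and without replicate 3 Aqp3 did (0.0395). YAP and TAZ targets were higher in 7 and lower in 1 of 23 (8 and 2 adjusted over the list alone, adjusted p = 0.0539), and Hippo components were higher in 7 of 24 (8 adjusted over the list alone, adjusted p = 0.0539).

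Extracellular matrix genes rose in 6 of 19 (7 adjusted over the list alone, adjusted p = 1.56e-07, and adjusted p = 0.0548 with an estimated correlation). Col4a2 (0.45 ± 0.04) and Col4a1 (0.33 ± 0.03) were among them. Cholesterol synthesis genes rose in 6 of 21 (8 adjusted over the list alone, adjusted p = 7.9e-07, and adjusted p = 0.334 with an estimated correlation), with Dhcr7 at 0.32 ± 0.05. The cAMP and CREB targets fell in 6 of 23 (9 adjusted over the list alone, adjusted p = 0.0152, and adjusted p = 0.334 with an estimated correlation), with Pde10a at -1.41 ± 0.30. Principal cell transport genes fell in 4 of 18 and rose in 1 (8 and 3 adjusted over the list alone, adjusted p = 0.0193, and adjusted p = 0.339 with an estimated correlation). Intercalated cell markers fell in 3 of 9 (3 adjusted over the list alone, adjusted p = 0.0193, and adjusted p = 0.316 with an estimated correlation), including Car2 (-0.31 ± 0.04). Actin genes rose in 6 of 26 and fell in 1 (7 and 3 adjusted over the list alone, adjusted p = 0.0221, and adjusted p = 0.565 with an estimated correlation). NRF2 and glutathione genes fell in 4 of 20 and rose in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.0339, and adjusted p = 0.366 with an estimated correlation), with Mt2 at -0.50 ± 0.07. Among markers of other nephron segments Podxl rose (0.50 ± 0.04) and Lrp2 fell (-0.30 ± 0.05) of 5 tested (2 and 1 adjusted over the list alone, adjusted p = 0.0339, and adjusted p = 0.267 with an estimated correlation).

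Without control siRNA dDAVP replicate 1 the adjusted p was 0.0629 for principal cell transport, NRF2 and other nephron segment genes, 0.0753 for intercalated cell markers and 0.1 for actin genes. It was 0.1 for NRF2 and 0.0594 for other segments without control siRNA dDAVP replicate 2, 0.0965 for both without TAZ siRNA dDAVP replicate 2, and 0.0834 for actin genes without TAZ siRNA dDAVP replicate 1. The epithelial junction list (3 higher and 4 lower of 27, adjusted p = 0.215) did not pass, although Krt19 (-0.45 ± 0.05) and Krt18 (-0.20 ± 0.04) fell. Its median was 0.0069 and its mean -0.03. A further 10 lists did not pass, with adjusted p-values from 0.0915 for interferon genes to 0.959 for oxidative phosphorylation.

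**Figure D3:**
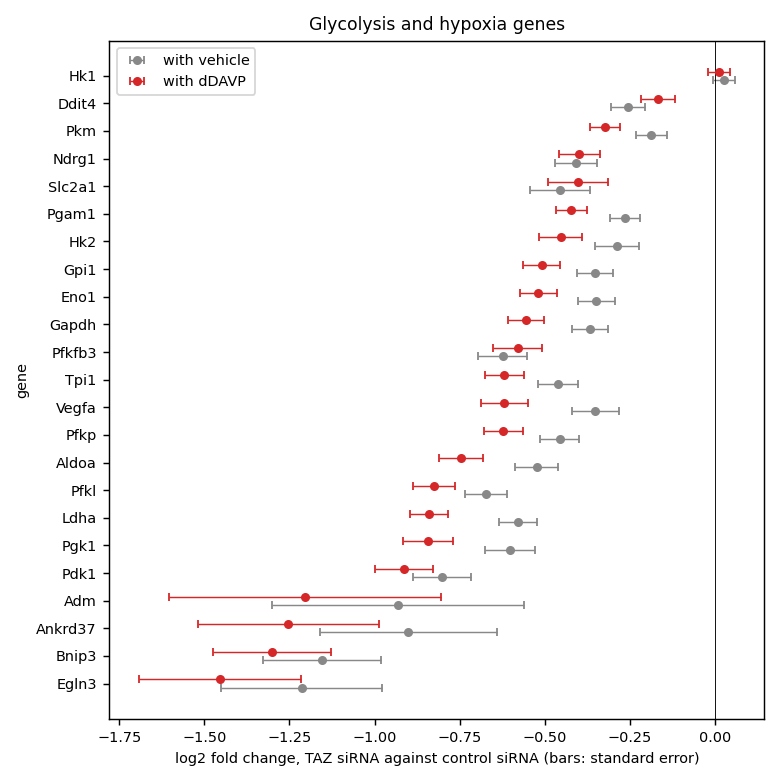
Log2 fold change ± SE of the 23 tested glycolysis and hypoxia genes, TAZ siRNA against control siRNA, with vehicle and with dDAVP. The medians are -0.46 and -0.62, and 20 and 21 of the genes were called lower.

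Between the treatments, 276 genes rose and 305 fell with TAZ siRNA in both, against 29.3 and 24.7 for independent lists, in comparisons that share no library. They share the estimate of spread per gene, so this reference may be too low as well. Fold changes across genes correlated with r = 0.169 and rho = 0.397. The 3 genes called in opposite directions, named after their values were seen, were Lyar (0.22 and -0.19), Cxcl5 (0.83 and -0.40) and Abcc3 (0.24 and -0.48).

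The fifth comparison tested whether the response to dDAVP differed between the siRNAs. The fall of the type IV collagen chains Col4a4 and Col4a1 was smaller with TAZ siRNA (differences of 0.41 ± 0.05 and 0.29 ± 0.05, adjusted p = 0.00374 and 0.044). The rise of the chemokine Cxcl5 (-1.23 ± 0.17, adjusted p = 0.032), of the transporter Abcc3 (-0.72 ± 0.09, adjusted p = 0.00374) and of the zinc transporter Slc39a4 (-0.53 ± 0.07, adjusted p = 0.00374) was smaller with TAZ siRNA. These 5 of 15932 genes were all that edgeR called, against 1295 at an unadjusted p under 0.05. DESeq2 called 98 genes, with 4 of the 5 among them and no adjusted p for Abcc3.

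Aqp2 did not differ detectably in its response (1.10 ± 1.11, adjusted p = 0.843), as the 9 counts with TAZ siRNA and vehicle left its fold with a wide interval. The difference was 0.25 ± 0.04 for Scnn1a (adjusted p = 0.0594, and 0.000133 in DESeq2 and 0.0398 with the stricter filter), -0.05 ± 0.10 for Avpr2 (adjusted p = 0.945) and 0.01 ± 0.05 for Elf3 (adjusted p = 0.973). Of the lists, 9 passed at the preset correlation, among them NRF2 and glutathione genes (adjusted p = 7.3e-09, and adjusted p = 0.13 with an estimated correlation, 7 lower adjusted over the list alone) and cAMP and CREB targets (adjusted p = 4.45e-05, and adjusted p = 0.167 with an estimated correlation, 6 lower adjusted over the list alone). All 9 calls were lost with an estimated correlation, at adjusted p-values from 0.13 to 0.587. The YAP and TAZ target list did not pass (adjusted p = 0.0537). The call of Col4a1 ended in 12 and that of Cxcl5 in 9 of 19 alternatives, with adjusted p-values up to 0.171 without control siRNA dDAVP replicate 3 and 0.138 without TAZ siRNA dDAVP replicate 1. The count of called genes was 3 without control siRNA vehicle replicate 3, control siRNA dDAVP replicate 3 or TAZ siRNA dDAVP replicate 1. It was 8 without TAZ siRNA dDAVP replicate 2, 9 without control siRNA dDAVP replicate 1, 11 without control siRNA vehicle replicate 1 and 19 without TAZ siRNA vehicle replicate 1.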

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

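Of the tests used here, those of spread between libraries and of a weaker cAMP signal, and the counts over other splits of the libraries, were chosen only after the results were seen. Col4a4 and Col4a1 fell on dDAVP with both siRNAs, and the test of the difference between the responses gave 0.41 (adjusted p = 0.00374) and 0.29 (adjusted p = 0.044) in edgeR. The same test gave -1.23 for Cxcl5 (adjusted p = 0.032), -0.72 for Abcc3 (adjusted p = 0.00374) and -0.53 for Slc39a4 (adjusted p = 0.00374), which rose on dDAVP with both siRNAs. The calls of Col4a4, Abcc3 and Slc39a4 held in each alternative that gave them a value, with adjusted p-values up to 0.0379, 0.0243 and 0.0243. That of Col4a1 was lost without control siRNA vehicle replicates 2 and 3 (0.119 and 0.122), control siRNA dDAVP replicates 2 and 3 (0.122 and 0.171), TAZ siRNA vehicle replicates 2 and 3 (0.13 and 0.0735) and TAZ siRNA dDAVP replicates 1, 2 and 3 (0.138, 0.0538 and 0.0924). That of Cxcl5 was lost without control siRNA vehicle replicates 1 and 3 (0.0657 and 0.122), control siRNA dDAVP replicates 1, 2 and 3 (0.066, 0.0689 and 0.0694), TAZ siRNA vehicle replicate 3 (0.062) and TAZ siRNA dDAVP replicates 1, 2 and 3 (0.138, 0.0538 and 0.0924).

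The difference of the responses also passed camera for 9 lists. The medians were -0.20 for cAMP and CREB targets (adjusted p = 4.45e-05), -0.12 for NRF2 and glutathione genes (7.3e-09), -0.16 for glycolysis and hypoxia genes (5.25e-06) and -0.10 for NF-kappaB and cytokine genes (0.00216). They were -0.044 for cholesterol synthesis (0.0299), -0.0345 for oxidative phosphorylation (0.0191), -0.0767 for p53 targets (0.0299) and 0.0767 for interferon genes (0.0474). Extracellular matrix genes had a median of 0.0713 (0.012), in the direction of the test, and a mean of -0.10. With an estimated correlation the adjusted p-values were, in this order, 0.167, 0.13, 0.426, 0.191, 0.587, 0.587, 0.167, 0.587 and 0.288. Leaving out single libraries also ended 5 of these calls. Without control siRNA vehicle replicate 2 the adjusted p was 0.242 for cholesterol synthesis, 0.276 for oxidative phosphorylation, 0.076 for p53 targets and 0.0684 for interferon and extracellular matrix genes. Without control siRNA vehicle replicates 1 and 3 it was 0.14 for interferon genes and 0.056 for p53 targets. Without control siRNA dDAVP replicate 1 it was 0.0535 for cholesterol synthesis, 0.199 for interferon genes and 0.0837 for p53 targets, and without replicate 2 it was 0.168 for interferon genes and 0.203 for oxidative phosphorylation. Without TAZ siRNA vehicle replicate 2 it was 0.113 for cholesterol synthesis, and without replicate 3 it was 0.197 for that list, 0.367 for interferon genes, 0.196 for oxidative phosphorylation and 0.115 for p53 targets. Without TAZ siRNA dDAVP replicates 1 and 3 it was 0.0532 and 0.0538 for p53 targets, without replicate 2 it was 0.405 for cholesterol synthesis and 0.278 for oxidative phosphorylation, and without replicate 3 it was 0.949 for interferon genes.

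The response to dDAVP was smaller with TAZ siRNA over the 4162 genes that responded on average, at 83.0% of the response with control siRNA. Gene by gene, the response was smaller with TAZ siRNA in 68.7% of them, and how far noise in single genes shaped this share was not tested. For the number of called genes depth was argued against, since the ratio, control siRNA to TAZ siRNA, was 1.75 (2977 against 1703) with all libraries thinned to the same total and 1.78 before. The size of the response was not computed again on thinned counts, so depth was not tested as a cause of the 83.0%. Spread between libraries was argued against, since the mean log2 response of these genes differed by -0.0564 (95% interval -0.0968 to -0.016), with an upper bound of at most -0.00624 without single libraries. Of the other sets, the ratio was 0.837 for 20 cAMP and CREB targets (interval of the difference -0.374 to -0.138), 0.732 for 19 NRF2 and glutathione genes (-0.242 to -0.057), 0.706 for extracellular matrix (-0.184 to -0.0275), 0.831 without the glycolysis list (-0.0964 to -0.0157), 0.537 for glycolysis (-0.363 to 0.0386) and 1.01 for 12 principal cell transport genes (-0.225 to 0.213), or 0.923 without Aqp2 (-0.216 to 0.0264), left out after its 9 counts with TAZ siRNA and vehicle were seen. A weaker signal upstream of cAMP target genes stays open as a hypothesis. It could make all responses to dDAVP smaller alike. A ratio of 0.837 beside 83.0% for all responding genes does not argue against it. The share of 68.7% and the set ratios of 0.537 to 1.01 do not show that all responses shrank alike. The ratio of 0.837 also does not tell a weaker signal from another cause of smaller responses. A difference in culture that follows the siRNA was not tested.

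With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 3058 genes on dDAVP with control siRNA, 1719 with TAZ siRNA, 1004 for TAZ siRNA with vehicle and 1711 for TAZ siRNA with dDAVP, and the highest other split gave 1, 0, 0 and 2. In each case 1 split, the real one, gave as many. Each other split put libraries of both compared groups together, so the real difference entered the spread, which by itself lowers the calls. These counts therefore do not show whether chance can be excluded. For the difference of responses 4 of 100 splits, the real one included, gave at least the real 5 genes, and the highest other split gave 3031. The 99 other splits mixed the treatments and so carried the response to dDAVP, a structure of the samples, and they do not show whether chance can be excluded for these 5 genes.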

How the results depend on the processing

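All alternatives reported here were planned. Of 400 called gene results, 303 kept their call in every alternative that gave a value, 97 lost it in at least 1 and 0 reversed in edgeR, DESeq2 or limma-voom. The difference of responses, 5 genes, became 98 with DESeq2, 12 with no low-count filter and 20 with the stricter filter, and 3 to 19 without single libraries. With DESeq2 7925 genes and with the stricter filter 12579 genes received an adjusted p, against 15932, but no filter tested 24656 and also called more, so the cause was not tested. Without single libraries the counts were 2129 to 2710 for dDAVP with control siRNA, 1129 to 1763 for dDAVP with TAZ siRNA, 414 to 1453 for TAZ siRNA with vehicle and 1065 to 1652 for TAZ siRNA with dDAVP. Fewer samples entered each of these fits, but the count for TAZ siRNA with vehicle rose to 1453 without replicate 1 of that group, and the cause was not tested. The lists that passed numbered 64 of 110, 13 with an estimated correlation, 54 with fry in one direction, 94 in either direction and 53 to 69 without single libraries. Of the 64 calls, fry in one direction kept 46 and lost 18, among them every list that had passed for the difference of responses. Agreement between responses was 1103 and 517 genes among the 9610 genes at 10 CPM or more, against 1300 and 581 among all 15932 tested. At the depth reached, Aqp2 with vehicle rested on 55 and 9 counts per group. Its change with TAZ siRNA was called by DESeq2 (adjusted p = 0.000148) and not by edgeR (adjusted p = 0.152). Both tools used the same libraries, so depth does not explain why they differed on this call. With vehicle, total counts per library were 60715300 to 61725300 with TAZ siRNA and 47072900 to 58226100 with control siRNA. Lower depth thus does not explain the lower Aqp2 counts with TAZ siRNA. Whether the spread between libraries caused the differing calls, and whether deeper libraries would change the edgeR result, was not tested.

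Libraries share only a replicate number. Those of the same number deviated together with a mean correlation of 0.017 (-0.043 to 0.080), against -0.0086 for other pairs, and 7 of 12 correlated best with their own number, a hint from the data and not the design. With the number as a block the counts were 2983, 1663, 968, 1690 and 6 in the order of the comparisons, 63 lists passed, and 1283 and 573 genes were shared. Of the 64 lists 62 kept their call, while NRF2 and glutathione genes and other nephron segment markers lost theirs for TAZ siRNA with dDAVP (both adjusted p = 0.0566). Among results of genes that could be named, 11 lost their call, including the difference of responses of Col4a1 (adjusted p = 0.0631). For TAZ siRNA with vehicle 479 genes were higher and 489 lower, and Scnn1g (0.0407) and Gata3 (0.0429) passed, as Gata3 did with dDAVP (0.0441).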

Other observations

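Of the tests used here, those of library depth and spread between libraries for the glycolysis genes, of noise and of Yap1 were chosen only after the results were seen. The genes for the test of hypoxia-inducible transcription were listed after the glycolysis result was seen but before their own values were. With TAZ siRNA, 8 of 21 tested hypoxia-inducible genes outside the fixed list were lower with vehicle and 14 with dDAVP, and none was higher in edgeR. Egln1, a prolyl hydroxylase that senses oxygen, changed by -0.47 and -0.55, Plod2, a collagen lysyl hydroxylase, by -0.33 and -0.55, and Fam162a by -0.54 and -1.01. P4ha1 and P4ha2, subunits of collagen prolyl hydroxylases, changed by -0.42 and -0.57 and by -0.44 and -0.67.

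The glycolysis and hypoxia list was lower with TAZ siRNA in both treatments. GC content and transcript length were argued against as the whole cause, since the median was -0.48 with vehicle and -0.62 with dDAVP after that trend was removed, against -0.46 and -0.62 before, with values for all 23 members. Depth was argued against too, as the log2 ratio of depth was 0.18 with vehicle and -0.21 with dDAVP while the list was lower in both, and so was spread between libraries unrelated to the siRNA, with an exact permutation p of 0.005, the smallest that 400 assignments can give. Lower activity of hypoxia-inducible transcription is a candidate explanation, as genes outside the list had medians of -0.17 and -0.27 (camera adjusted p = 2.62e-13 and 4.28e-20, and adjusted p = 0.0127 and 0.00759 with an estimated correlation). A difference between cultures, cell density, medium or plates that follows the siRNA stays open, since the labels do not say whether libraries came from separate cultures, and was not tested. The TAZ siRNA libraries all carry the same siRNA label, so an effect through Wwtr1 cannot be told from another effect of the siRNA.

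The YAP and TAZ target list was not lower although Wwtr1 was. Noise that hides a fall as large as that of Wwtr1 was argued against, because the difference of the list means of log2 CPM per library was -0.0074 with vehicle (95% interval -0.0594 to 0.0446) and 0.0383 with dDAVP (-0.0137 to 0.0904), against -0.63 and -0.54 for Wwtr1. Smaller falls of the list, within these intervals, are not excluded, and how far it should fall with this loss of Wwtr1 was not tested. More Yap1 mRNA in place of Wwtr1 mRNA was argued against by an upper bound of 0.0565 for the change of Yap1. Protein of TAZ and YAP was not analysed here, and no biological explanation was tested.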
